A study of Homo sapiens with 16 samples.

How the data were processed

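RNA of HT-1080 cells, an established human fibrosarcoma line, was measured in 16 libraries. Per the labels' protocols, the cells were grown in DMEM with serum, erastin was given at 10 µM for 24 h, RNA was extracted with Trizol and amplified with Smart-seq v4, libraries were made with a NEBNext Ultra DNA kit, and sequencing was on a BGISEQ500. Per the labels, 4 genotypes (siNS, siDCAF8, oeWDR76 and siDCAF8+siLSH) without and with erastin give 8 groups of 2 libraries. The erastin treatment text stands in every label, so the group names decided which libraries were treated. No empty-vector library accompanies oeWDR76. The labels do not pair the libraries across groups, and the number of siRNAs per target is not given in the sources used here.

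The deposited table holds FPKM per gene and library, rounded to 2 decimals, which the authors made with StringTie on GRCh38 per the submitters' processing notes. The StringTie version, the aligner and the annotation release are not given in the sources used here. The table has 24107 entries, of which 17552 genes carry values and 6555 are empty. Symbols that a spreadsheet had turned into dates were restored for 28 genes. Gene numbers matched the RefSeq gene table for 17506 genes, all transcripts named in the table are coding RefSeq transcripts, and 0 genes lie on the mitochondrial chromosome. The deposited table gives no counts or depths, so the depth is unknown from the sources, and no interval or detection limit from counting is given. Between the 2 libraries of a group, Pearson's r of log2(FPKM + 1) was 0.996 to 0.997, which with the median SD of 0.05 to 0.07 log2 is the precision known here.

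The values were tested as log2(FPKM + 1) for 11260 genes with a mean of at least 1 FPKM over the 16 libraries. A linear model with 8 group means was fitted with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit, and eBayes with a mean-variance trend, not robust), with 8 residual and 8.57 prior degrees of freedom. The 15 contrasts were 12 comparisons of 2 groups and 3 differences of erastin responses. All tests were two-sided, p-values were adjusted by Benjamini-Hochberg within each contrast, and an adjusted p under 0.05 was called. Folds are 2 to the power of the log2 difference. Python 3.11.15 with pandas 2.3.3 and numpy 2.4.6 prepared the tables, and matplotlib 3.10.9 drew the plots. The model was tested on simulated data: of 200 genes moved in each of 20 datasets, 93.9% were called at a log2 change of 0.5 and 99.9% at 1, with 5.5% of calls false. A list of 30 genes moved by 0.3 was called in 20 of 20 datasets, and 2% of 400 random lists had p under 0.05. The genes were simulated as independent, with no trend on GC content. These values therefore say nothing of lists whose members vary together.

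Of 30 gene lists written by hand, 26 had at least 5 tested members and were tested with limma's camera at a preset correlation of 0.01, adjusted over all 390 tests, and again with the correlation estimated from the data. Members were also adjusted over the list alone. Genes named by rule are the 3 targeted genes and the 10 largest rises and 10 largest falls among called genes of each contrast. In comparisons of 2 groups, those rises and falls also had to show no overlap between the values of the groups. Each list, called or not, added up to 4 called members with the lowest p, or 2 members where none was called. Genes whose reads are shared with a close paralog or a read-through transcript are uncertain in FPKM and were left out of the text where others could be named. Some items that the rule names are not reported here. Overlaps of 2 effects were set beside the overlap of independent calls, and for effects that share libraries also beside simulated values with no effect.

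The comparisons, thresholds, gene lists, alternatives and the rule for named genes were set before the data were examined. The correction for GC content and transcript length and the counts of genes past 2-fold were chosen after the data were seen. The other alternatives were a pseudocount of 0.1, no filter on low values, a stricter filter of mean FPKM at least 5, median-ratio scaling over genes of at least 1 FPKM, quantile normalization, replicate number as a block, a fit of only the groups compared, and leaving out each library in turn. GC content was known for 11173 of the 11260 genes.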

Results

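HT-1080 is an established human fibrosarcoma line that is sensitive to ferroptosis, an iron-dependent death driven by lipid peroxidation. The 16 libraries form 8 groups of 2. Cells received the control siRNA (siNS), an siRNA against DCAF8 (siDCAF8), overexpression of WDR76 (oeWDR76), or siRNAs against DCAF8 and LSH together (siDCAF8+siLSH), each without or with erastin, which blocks cystine uptake by system xc-. DCAF8 is a substrate receptor of CRL4 ubiquitin ligases, WDR76 is a WD40-repeat protein of similar kind, and LSH is a chromatin remodeler encoded by HELLS. The oeWDR76 libraries stood apart on the first principal component, which held 53.8% of the variance, with scores of 45.7 to 48.8 against -26.0 to -8.9 in the other 12. The siNS libraries stood apart on the second component, which held 24.4%. Library totals ran from 436290 to 503867 FPKM, and from 495857 to 503867 in oeWDR76. Relative to each gene's mean over the 16 libraries, levels in oeWDR76 libraries rose with GC content, by 0.19 to 0.23 log2 per 10% GC. In the others this relative slope was -0.16 to 0.03. The labels give no preparation batches, so a batch holding only the oeWDR76 libraries could not be told apart from an effect of WDR76. Values below are mean ± SD of n = 2 libraries, folds are on the scale of FPKM plus 1, and SE is on the log2 scale. Nothing in the labels says that the 2 libraries of a group came from separate cultures, so every p-value measures only the spread between these libraries. Of 390 list tests, 150 passed with the preset correlation of 0.01 and 3 passed with an estimated correlation. With median-ratio scaling, rises made up 48.5% to 50.6% of called genes in each contrast except erastin in oeWDR76, where they made up 27.3%, so the other splits into higher and lower below depend on the scaling.

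The first question is whether each intended change reached the RNA. On GRCh38, DCAF8 (gene 50717) lies on chromosome 1 at 160215715 to 160262560, HELLS (gene 3070) on chromosome 10 at 94545767 to 94602099, and WDR76 (gene 79968) on chromosome 15 at 43826914 to 43868419. DCAF8 fell 3.12-fold in siDCAF8 without erastin (SE 0.08, adjusted p = 1.41e-10), from 39.7 ± 1.08 to 12 ± 0.304 FPKM, and 3.26-fold with erastin (adjusted p = 5.83e-11). In siDCAF8+siLSH it fell by 1.28 and 1.17 on the log2 scale against siNS (adjusted p = 1.06e-09 and 3.66e-09), and stood at 15.8 ± 2.23 FPKM without erastin. This depletion was weaker than in siDCAF8, by 0.37 without erastin (adjusted p = 0.00156) and 0.54 with it (adjusted p = 4.54e-05), so comparisons of siDCAF8+siLSH with siDCAF8 do not isolate LSH. WDR76 rose 64.0-fold in oeWDR76 (SE 0.11, adjusted p = 3.89e-17), from 3.21 ± 0.446 to 268 ± 0.446 FPKM, and 65.5-fold with erastin (adjusted p = 4.55e-17). HELLS fell 1.61-fold in siDCAF8+siLSH against siDCAF8 (SE 0.07, adjusted p = 1.59e-06), from 7.14 ± 0.438 to 4.06 ± 0.0141 FPKM, and 2.12-fold with erastin (adjusted p = 1.17e-08), from 5.87 ± 0.0283 to 2.24 ± 0.170 FPKM. Measured against siNS, HELLS in siDCAF8+siLSH without erastin was not called (log2 0.01, adjusted p = 0.884), and with erastin it was lower (-0.47, adjusted p = 2.14e-05).

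HELLS RNA itself was higher in siDCAF8 and oeWDR76. It rose 1.62-fold in siDCAF8 without erastin (adjusted p = 3.63e-07), from 4.02 ± 0.0495 FPKM in siNS, and 2.36-fold in oeWDR76 (adjusted p = 1.39e-10), to 10.9 ± 0.537 FPKM. With erastin the rises were 0.62 and 1.40 on the log2 scale (adjusted p = 1.12e-06 and 2.52e-11). Most G1/S and DNA replication genes also rose in both comparisons without erastin, as given below. The rise is thus not shown to be particular to HELLS, and oeWDR76 lacks an empty-vector control. Erastin lowered HELLS by 0.24 on the log2 scale in siDCAF8 (adjusted p = 0.0121) and by 0.64 in siDCAF8+siLSH (adjusted p = 1.37e-05), and left it uncalled in siNS (adjusted p = 0.0850) and oeWDR76 (adjusted p = 0.998). WDR76 also rose in siDCAF8, by 0.55 on the log2 scale (adjusted p = 0.000320), and in siDCAF8+siLSH, by 1.04 (adjusted p = 3.21e-07), both without erastin. With erastin WDR76 was not called in siDCAF8 (0.10, adjusted p = 0.419) and rose by 0.57 in siDCAF8+siLSH (adjusted p = 0.000201). DCAF8 fell in oeWDR76, by 0.31 on the log2 scale without erastin (adjusted p = 0.00265) and 0.23 with it (adjusted p = 0.0176).

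**Figure D1:**
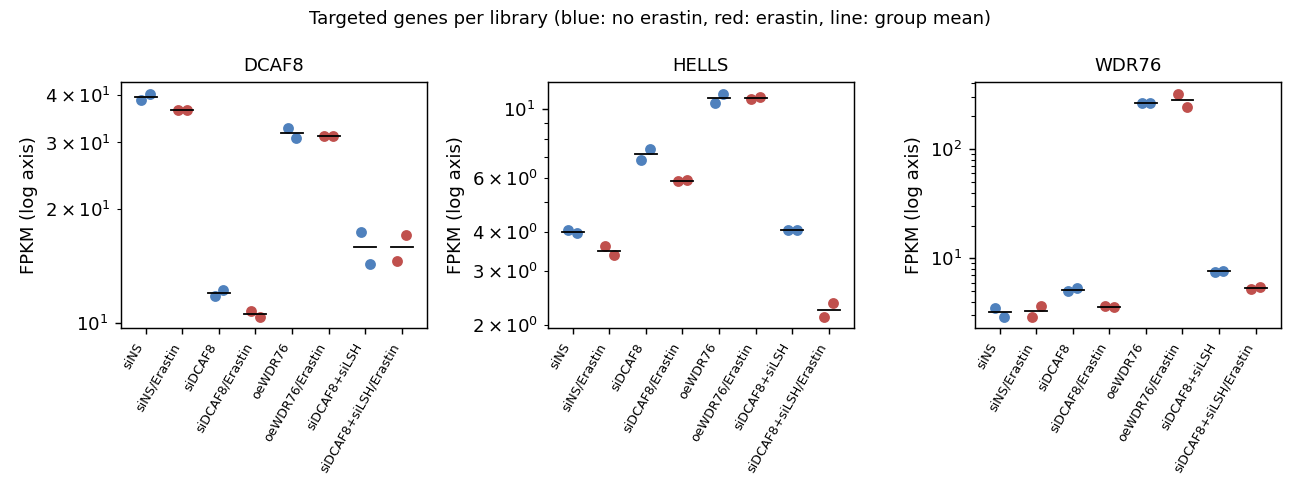
FPKM of DCAF8, HELLS (LSH) and WDR76 in each of the 16 libraries, on a log axis. Each group has n = 2 libraries, without and with erastin (10 µM, 24 h), and HELLS reaches 10.9 FPKM in oeWDR76 against 4.02 in siNS.

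Erastin in siNS asks which transcripts move in control cells when cystine uptake is blocked. HMOX1, the heme oxygenase that frees iron from heme, rose 10.5-fold (SE 0.30, adjusted p = 5.06e-07), from 14.7 ± 0.502 to 176 ± 92.3 FPKM. FTH1, the heavy chain of the iron store ferritin, rose 2.81-fold (SE 0.10, adjusted p = 2.11e-08), from 988 ± 1.34 to 2785 ± 235 FPKM. SQSTM1, an autophagy receptor that releases NRF2 from KEAP1, rose 2.46-fold, and GCLM, a subunit of the enzyme that starts glutathione synthesis, rose 2.41-fold. The chemokine CCL3 rose 4.07-fold. CHAC1, a glutathione-degrading target of ATF4, fell 6.70-fold (SE 0.14, adjusted p = 3.75e-09), from 35.8 ± 2.86 to 4.56 ± 1.2 FPKM. INHBE fell 4.19-fold, the mTORC1 inhibitor DDIT4 fell 4.02-fold, and TXNIP, which binds thioredoxin, fell 3.19-fold.

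Gene groups moved with them in siNS. Of 35 tested members of the ATF4 and amino acid response list, 25 fell and 2 rose (26 and 2 adjusted over the list alone), with a median log2 fold change of -0.49 (adjusted p = 5.77e-11, adjusted p = 0.348 with an estimated correlation). TRIB3, a pseudokinase induced by ATF4, fell by 1.43 on the log2 scale. All 30 mitosis genes fell (30 adjusted over the list alone), with a median of -0.65 (adjusted p = 2.67e-21, adjusted p = 0.2 with an estimated correlation), among them KIF20A and CENPE at -1.03 each and HMMR at -1.06. Of 26 NRF2 targets, 15 rose and 1 fell (16 and 1 adjusted over the list alone), with a median of 0.29 (adjusted p = 2.72e-08, adjusted p = 0.118 with an estimated correlation). Heat shock genes rose in 16 of 17 cases (16 adjusted over the list alone), with a median of 0.43 (adjusted p = 1.67e-13, adjusted p = 0.0659 with an estimated correlation), led by HSPB8 at 1.14 and HSPH1 at 0.96. In all, 4223 of 11260 tested genes were called, 1704 higher and 2519 lower, and 66 of them by at least 2-fold. That split was 2234 higher and 2058 lower with quantile normalization, and 2463 and 2126 after correction for GC content and transcript length. Without siNS replicate 2 the total was 2796.

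Erastin in siDCAF8 asks whether loss of the ligase receptor alters that response. HMOX1 rose 3.72-fold (SE 0.30, adjusted p = 0.000128), from 10.3 ± 0.191 to 43.9 ± 22.7 FPKM. ANKRD1, a YAP target, rose 2.74-fold (SE 0.08, adjusted p = 7.83e-09), from 324 ± 8.47 to 890 ± 21.3 FPKM, and the prostaglandin E synthase PTGES rose 3.30-fold. ASNS, the asparagine synthetase that ATF4 induces, rose 2.26-fold (SE 0.13, adjusted p = 5.47e-06), from 28.5 ± 2.68 to 66.4 ± 16.7 FPKM. The secreted hypoxia target STC1 fell 2.41-fold (SE 0.06, adjusted p = 4.63e-09), from 86.4 ± 2.37 to 35.3 ± 2.82 FPKM. Here 20 of 35 ATF4 list members rose and 1 fell (22 and 1 adjusted over the list alone), with a median of 0.38 (adjusted p = 2.16e-07, adjusted p = 0.518 with an estimated correlation). Of 29 genes of the G1/S transition and DNA replication, 24 fell (24 adjusted over the list alone), with a median of -0.47 (adjusted p = 1.36e-11, adjusted p = 0.193 with an estimated correlation), including TK1 at -0.89, RRM2 at -0.90 and E2F1 at -0.85. Mitosis genes fell in 28 of 30 cases (29 adjusted over the list alone), with a median of -0.53 (adjusted p = 5.89e-16, adjusted p = 0.217 with an estimated correlation). Of 23 glycolysis genes, 15 fell (15 adjusted over the list alone), with a median of -0.29 (adjusted p = 0.000468, adjusted p = 0.193 with an estimated correlation), including PGAM1 at -0.73 and LDHA at -0.64. After correction for GC content and length that median was -0.17. GC content and length held 21.7% of the variance of this erastin effect across genes, and 2896 of its 4600 calls kept their direction after the correction. The calls numbered 4600, with 2065 higher and 2535 lower (1979 and 1958 after the correction), and 29 by at least 2-fold. Without siDCAF8 replicate 1 the total was 3021, and without siDCAF8/Erastin replicate 2 the genes past 2-fold were 45.

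The interaction test asks which erastin responses differ between siDCAF8 and siNS. SLC7A11, the transporter subunit of system xc- that erastin inhibits, went from 5.65 ± 0.304 to 2.36 ± 0.474 FPKM in siNS and from 6 ± 1.10 to 12.4 ± 4.32 FPKM in siDCAF8. Its response was 1.90 higher on the log2 scale in siDCAF8 (SE 0.23, adjusted p = 5.44e-05). CTH, which makes cysteine from cystathionine, differed by 1.94 (SE 0.15, adjusted p = 1.2e-06), with 8.83 ± 0.665 to 4.02 ± 0.248 FPKM in siNS and 9.23 ± 1.52 to 19.0 ± 3.39 FPKM in siDCAF8. CHAC1 differed by 2.49 (SE 0.20, adjusted p = 1.78e-06), although in siDCAF8 it already stood at 6.68 ± 0.743 FPKM without erastin and at 5.44 ± 0.120 FPKM with it. Across the ATF4 list, 31 of 35 responses were higher in siDCAF8 (32 adjusted over the list alone), by a median of 1 (adjusted p = 4.27e-27, adjusted p = 0.183 with an estimated correlation). The heat shock response was smaller in siDCAF8 for 12 of 17 genes (14 adjusted over the list alone), by a median of -0.42 (adjusted p = 1.61e-11, adjusted p = 0.0774 with an estimated correlation), with HSPH1 at -0.89. The heat shock list was already called higher in untreated siDCAF8 than in untreated siNS, by a median of 0.28. That call was lost with a pseudocount of 0.1 (adjusted p = 0.0503), the stricter filter (adjusted p = 0.0874) and a fit of only the groups compared (adjusted p = 0.0529). A higher start is thus not told apart from a smaller heat shock response. HMOX1 rose less in siDCAF8, by -1.49 (SE 0.42, adjusted p = 0.0194). That HMOX1 call was lost without siNS replicate 1 (-1.46, adjusted p = 0.0645), siNS/Erastin replicate 2 (-0.94, adjusted p = 0.0837), siDCAF8 replicate 1 (-1.48, adjusted p = 0.0557) or siDCAF8/Erastin replicate 2 (-0.95, adjusted p = 0.0909), and with no filter on low values (adjusted p = 0.1). The interaction called 2341 genes, 1233 with a higher and 1108 with a lower response in siDCAF8, against 1329 without siNS replicate 1, 1315 without siNS/Erastin replicate 1 and 1532 without siDCAF8 replicate 1.

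Erastin in oeWDR76 asks the same of cells with excess WDR76. ANKRD1 rose 1.92-fold (SE 0.08, adjusted p = 1.87e-05), from 51.7 ± 0.149 to 100 ± 1.70 FPKM. CHAC1 fell 2.05-fold (SE 0.14, adjusted p = 0.00153), from 40.6 ± 2.84 to 19.2 ± 0.304 FPKM. HMOX1, at 16.6 ± 0.219 and 22.2 ± 2.72 FPKM, and FTH1, at 1002 ± 35.7 and 1141 ± 38.4 FPKM, were not called (adjusted p = 0.595 and 0.412). Of 35 ATF4 list members 14 fell (29, with 1 rise, adjusted over the list alone), by a median of -0.35 (adjusted p = 6.13e-28, adjusted p = 0.183 with an estimated correlation). Interferon-stimulated genes fell in 7 of 30 cases (15 adjusted over the list alone), by a median of -0.19 (adjusted p = 1.10e-14), and that list call held at adjusted p = 0.0188 with an estimated correlation. OAS3, a sensor of double-stranded RNA, fell by 0.49 on the log2 scale (adjusted p = 0.00115). The mitosis genes had a median of -0.04, and their list was not called (adjusted p = 0.261), though it was called lower after correction for GC content and length (-0.04, adjusted p = 0.0317). Only 163 genes were called, 53 higher and 110 lower, while 1527 had an unadjusted p under 0.05. The total was 38 without oeWDR76 replicate 1, 27 without oeWDR76 replicate 2, 32 without oeWDR76/Erastin replicate 1 and 39 without oeWDR76/Erastin replicate 2. Past 2-fold were 6 genes, all lower. With no filter on low values 5 genes passed 2-fold, 2 higher and 3 lower.

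Tested directly against siNS, the oeWDR76 response to erastin was smaller for several of the genes named in siNS. HMOX1 differed by -2.99 (SE 0.42, adjusted p = 0.000373), FTH1 by -1.30 (SE 0.14, adjusted p = 6.31e-05) and SQSTM1 by -1.09 (adjusted p = 5.68e-05). CHAC1 fell less, by 1.70 (SE 0.20, adjusted p = 0.000118), as did DDIT4, by 1.44 (adjusted p = 0.000151). All 30 mitosis genes fell less (30 adjusted over the list alone), by a median of 0.64 (adjusted p = 8.42e-27, adjusted p = 0.183 with an estimated correlation), including KIF20A at 0.88 and HMMR at 0.95. Of 26 NRF2 targets, 10 rose less (14, with 1 rising more, adjusted over the list alone), by a median of -0.30 (adjusted p = 5.21e-08, adjusted p = 0.118 with an estimated correlation). Of 17 heat shock genes, 9 rose less (13 adjusted over the list alone), by a median of -0.29 (adjusted p = 7.02e-11, adjusted p = 0.0774 with an estimated correlation). The median level over the 19 heat shock members in the data was already 51.6 FPKM in untreated oeWDR76, against 25.6 in siNS and 39.9 in siNS/Erastin. For this list a higher start is therefore not told apart from a weaker response. The test called 1593 genes, 1018 higher and 575 lower. The split was 793 and 778 with median-ratio scaling, 804 and 837 with quantile normalization, and 974 and 1005 after correction for GC content and length. The total was 988 without siNS replicate 1, 956 without siNS replicate 2, 935 without siNS/Erastin replicate 1, 976 without oeWDR76 replicate 1, 906 without oeWDR76 replicate 2, 958 without oeWDR76/Erastin replicate 1 and 927 without oeWDR76/Erastin replicate 2.

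**Figure D2:**
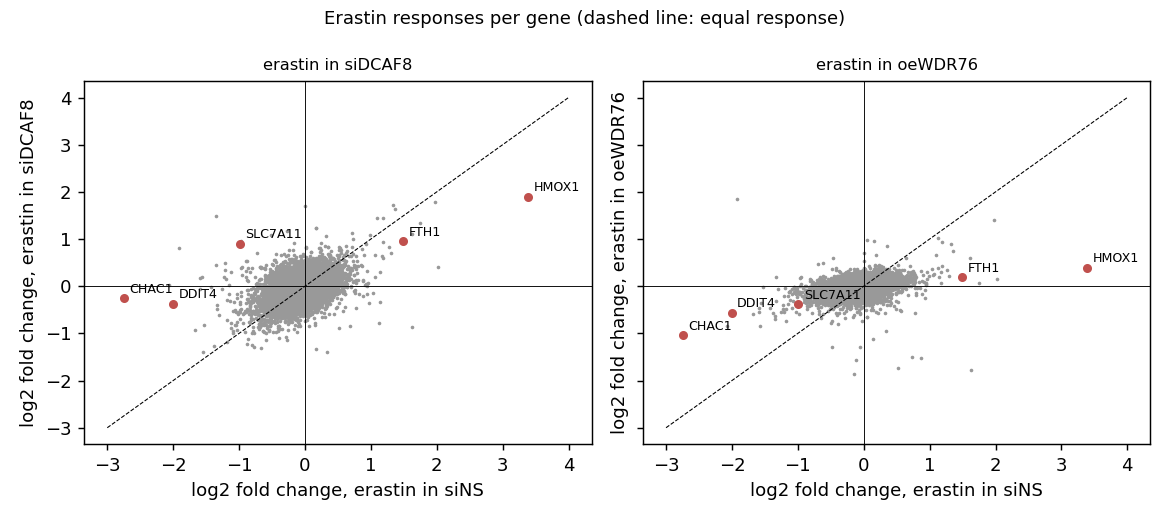
Log2 fold change after erastin of each tested gene in siNS against siDCAF8 (left) and against oeWDR76 (right). Named points are HMOX1, CHAC1, FTH1, SLC7A11 and DDIT4, and the dashed line marks an equal response. HMOX1 lies at 3.39 in siNS, 1.90 in siDCAF8 and 0.40 in oeWDR76, with n = 2 libraries per group.

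Erastin in siDCAF8+siLSH asks how cells given both siRNAs respond. HMOX1 rose 20.3-fold (SE 0.30, adjusted p = 1.93e-07), from 9.76 ± 2.74 to 215 ± 34.2 FPKM. FTH1 rose 3.10-fold (SE 0.10, adjusted p = 5.49e-08), from 511 ± 6.58 to 1588 ± 116 FPKM, and GDF15, a stress-induced cytokine, rose 2.75-fold (SE 0.09, adjusted p = 5.49e-08), from 342 ± 27.0 to 941 ± 40.1 FPKM. GPX4, the peroxidase that removes lipid peroxides, rose by 0.40 on the log2 scale (adjusted p = 5.43e-05). RRM2, a subunit of ribonucleotide reductase, fell 1.77-fold (SE 0.08, adjusted p = 4.64e-06), from 68.9 ± 2.04 to 38.6 ± 4.99 FPKM, and the lamin gene LMNB1 fell by 0.85 on the log2 scale. Of 35 ATF4 list members, 26 rose (30, with 1 fall, adjusted over the list alone), by a median of 0.38 (adjusted p = 1.59e-14, adjusted p = 0.245 with an estimated correlation). NRF2 targets rose in 14 of 26 cases (15, with 1 fall, adjusted over the list alone), by a median of 0.25 (adjusted p = 3.73e-10, adjusted p = 0.0774 with an estimated correlation). Of 23 autophagy and lysosome genes, 11 rose (11 adjusted over the list alone), by a median of 0.15 (adjusted p = 0.000246, adjusted p = 0.183 with an estimated correlation), including SQSTM1 at 1.04. All 30 mitosis genes fell (30 adjusted over the list alone), by a median of -0.64 (adjusted p = 1.15e-34, adjusted p = 0.164 with an estimated correlation), and 25 of 29 G1/S genes fell (28 adjusted over the list alone), by a median of -0.42 (adjusted p = 2.84e-20, adjusted p = 0.140 with an estimated correlation). Erastin moved 2270 genes here, 1196 up and 1074 down (1161 and 1340 after correction for GC content and length), against 1247 without siDCAF8+siLSH replicate 2, 1423 without siDCAF8+siLSH/Erastin replicate 1 and 1281 without siDCAF8+siLSH/Erastin replicate 2.

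Whether the erastin response differs between siDCAF8+siLSH and siDCAF8 was tested as a difference of responses, beside the difference in DCAF8 level given above. HMOX1 rose more in siDCAF8+siLSH, by 2.45 (SE 0.42, adjusted p = 0.00242), and by 2.22 after correction for GC content and length (adjusted p = 0.0229). FTH1 rose more by 0.67 (SE 0.14, adjusted p = 0.00481), and FPR1, a formyl peptide receptor, differed by 1.5 (adjusted p = 2.52e-05). CA9, a carbonic anhydrase induced by hypoxia, differed by 1.33 (SE 0.18, adjusted p = 0.000895), or by 2.83 with a pseudocount of 0.1. Its level was already low without erastin in both siDCAF8 and siDCAF8+siLSH, as the comparisons with siNS below show. The transcription factor gene MYBL1 differed by -0.85. HELLS fell more, by -0.40 (adjusted p = 0.0126), a call lost after correction for GC content and length (-0.16, adjusted p = 0.389), without siDCAF8 replicate 1 (adjusted p = 0.0613) and without siDCAF8+siLSH/Erastin replicate 1 (adjusted p = 0.0511). Of 23 glycolysis genes, 11 had a higher and 1 a lower response (13 and 1 adjusted over the list alone), by a median of 0.23 (adjusted p = 7.91e-05, adjusted p = 0.183 with an estimated correlation). After the correction the median was 0.13, with 3 higher and 0 lower. GC content and length accounted for 50.4% of the variance of this difference across genes. The test called 2642 genes, 1602 higher and 1040 lower. The correction gave 265 genes, 123 higher and 142 lower, of which 215 were among the 2642 in the same direction. The split was 1330 and 1336 with median-ratio scaling and 1385 and 1387 with quantile normalization. The total was 1008 without siDCAF8 replicate 1, 1624 without siDCAF8/Erastin replicate 2, 1201 without siDCAF8+siLSH replicate 2 and 1470 without siDCAF8+siLSH/Erastin replicate 1. Of the called genes 11 passed 2-fold, against 26 without siDCAF8+siLSH replicate 1 and 20 without siDCAF8+siLSH/Erastin replicate 1.

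Genes that erastin moved in all 4 genotypes form the shared part of the response. ANKRD1 rose by 1.18 in siNS, 1.46 in siDCAF8, 0.94 in oeWDR76 and 1.04 in siDCAF8+siLSH on the log2 scale. Chosen after their values were seen, HIF1A rose by 0.59, 0.47, 0.34 and 0.32 in the same order, and STC1 fell by 1.38, 1.27, 0.57 and 0.80. In total 18 genes rose in all 4 genotypes and 16 fell in all 4, where independent calls would give 0.16 and 0.53. Between siNS and siDCAF8, which share no library in this comparison, erastin effects correlated across genes at r = 0.435, with 670 genes higher and 1184 lower in both against 312 and 567 under independence. The correlation was 0.355 between siNS and oeWDR76, 0.232 between siNS and siDCAF8+siLSH, 0.407 between siDCAF8 and siDCAF8+siLSH (0.651 after correction for GC content and length), and 0.084 between oeWDR76 and siDCAF8+siLSH.

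The comparison of siDCAF8 with siNS asks what DCAF8 loss does in cells without and with erastin. No group restores DCAF8, so effects of the siRNA on other targets cannot be told apart from DCAF8 loss. NOLC1, a nucleolar chaperone, rose 5.15-fold without erastin (SE 0.05, adjusted p = 1.38e-14), from 18.2 ± 0.460 to 97.6 ± 1.68 FPKM, and UNG, the uracil-DNA glycosylase, rose 3.48-fold (adjusted p = 4.20e-10). CA9 fell 7.26-fold (SE 0.13, adjusted p = 4.92e-11), from 20.2 ± 0.495 to 1.92 ± 0.0495 FPKM. The gelatinase gene MMP9 fell 5.86-fold (SE 0.19, adjusted p = 1.01e-08), the matricellular YAP target CTGF 5.04-fold (SE 0.10, adjusted p = 2.02e-11), from 108 ± 3.98 to 20.7 ± 2.86 FPKM, and the chemokine CCL5 4.78-fold (adjusted p = 8.67e-11). With erastin, MMP9 was 11.3-fold lower in siDCAF8 and CA9 stood at -3.38 on the log2 scale, or -5.32 with a pseudocount of 0.1, while SLC7A11 was 3.90-fold higher (SE 0.16, adjusted p = 2.05e-08), at 12.4 ± 4.32 against 2.36 ± 0.474 FPKM, and CTH 3.97-fold higher (adjusted p = 1.88e-10).

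In siDCAF8 without erastin, 27 of 29 G1/S and DNA replication genes rose (27 adjusted over the list alone), by a median of 0.60 (adjusted p = 1.46e-09, adjusted p = 0.216 with an estimated correlation), including MCM3, a helicase subunit, at 1.26 and the licensing factor CDC6 at 1.45. Replication-dependent histones, whose weakly polyadenylated RNA also responds to how RNA is selected, rose in 6 of 7 cases and fell in 1 (6 and 1 adjusted over the list alone), by a median of 1.19 (adjusted p = 0.0022, adjusted p = 0.183 with an estimated correlation), or 0.04 with no filter on low values. With erastin their median was 0.69, a call lost with a pseudocount of 0.1 (adjusted p = 0.0606) and with no filter on low values (adjusted p = 0.313). Without erastin, hypoxia genes fell in 13 of 17 cases and rose in 1 (13 and 1 adjusted over the list alone), by a median of -0.49 (adjusted p = 0.000109, adjusted p = 0.217 with an estimated correlation). Of 30 interferon-stimulated genes, 21 fell (21 adjusted over the list alone), by a median of -0.31 (adjusted p = 0.000143, adjusted p = 0.183 with an estimated correlation). NF-kB targets fell in 8 of 12 cases and rose in 1 (8 and 1 adjusted over the list alone), by a median of -0.45 (adjusted p = 0.00108, adjusted p = 0.216 with an estimated correlation), or -0.76 with a pseudocount of 0.1 and -0.15 with no filter on low values. The ATF4 list was lower without erastin, with 20 of 35 members down and 2 up (20 and 2 adjusted over the list alone, median -0.28, adjusted p = 0.000531, adjusted p = 0.642 with an estimated correlation). With erastin it was higher, with 22 up and 4 down (22 and 5 adjusted over the list alone, median 0.49, adjusted p = 0.000283, adjusted p = 0.626 with an estimated correlation). Chaperones and other genes of the unfolded protein response were lower with erastin in 19 of 23 cases and higher in 2 (20 and 2 adjusted over the list alone, median -0.51, adjusted p = 4.60e-06, adjusted p = 0.216 with an estimated correlation), among them HSPA5, the main chaperone of the endoplasmic reticulum, at -1.27. Cholesterol synthesis genes were lower with erastin in 19 of 24 cases and higher in 1 (19 and 1 adjusted over the list alone, median -0.56, adjusted p = 7.56e-05, adjusted p = 0.581 with an estimated correlation). The comparison called 6863 genes without erastin, 3495 higher and 3368 lower with 337 past 2-fold, and 7293 with erastin, 3917 higher and 3376 lower with 490 past 2-fold.

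The comparison of oeWDR76 with siNS asks what excess WDR76 does, though no empty-vector group exists and siNS cells carried an siRNA instead. ISG15, a ubiquitin-like protein induced by interferon, rose 72.0-fold without erastin (SE 0.09, adjusted p = 1.71e-18), from 13.4 ± 1.33 to 1036 ± 25.2 FPKM, and IFI6 rose 70.8-fold (SE 0.09, adjusted p = 1.71e-18), from 16.2 ± 0.255 to 1220 ± 18.0 FPKM. The antiviral genes MX2 and IFIT1 rose 40.2-fold and 28.9-fold. TFRC, the transferrin receptor that brings iron into cells, fell 11-fold (SE 0.11, adjusted p = 9.66e-14), from 252 ± 7.50 to 22.2 ± 4.4 FPKM, and 11.1-fold with erastin. MMP9 fell 13.4-fold and CTGF 10.3-fold without erastin. With erastin, HMOX1 was 7.13-fold lower (SE 0.30, adjusted p = 1.74e-07). ACSL4, which loads membranes with oxidizable lipids, fell by 0.99 on the log2 scale without erastin (adjusted p = 1.69e-10).

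All 30 interferon-stimulated genes rose in oeWDR76 (30 adjusted over the list alone), by a median of 3.62 without erastin (adjusted p = 1.92e-18) and 3.32 with it (adjusted p = 9.40e-16), and each call held at adjusted p = 0.0188 with an estimated correlation. Among leukocyte markers, the T cell gene CD3E rose from 0.645 ± 0.00707 to 1.93 ± 0.0424 FPKM (log2 0.83, adjusted p = 7.15e-07, or 0.51 after correction for GC content and length and 1.45 with a pseudocount of 0.1), while LYZ, at 3.66 ± 0.00707 and 4.47 ± 0.240 FPKM, and PTPRC were not called (adjusted p = 0.0992 and 0.181). CD68, a macrophage marker that HT-1080 cells also express, rose from 109 ± 6.41 to 157 ± 5.41 FPKM (log2 0.53, adjusted p = 2.57e-06) and by 0.71 with erastin (adjusted p = 6.55e-08). All 29 G1/S and DNA replication genes rose (29 adjusted over the list alone), by a median of 1.18 without erastin (adjusted p = 3.12e-11, adjusted p = 0.2 with an estimated correlation) and 1.32 with it (adjusted p = 5.56e-10, adjusted p = 0.216 with an estimated correlation), led by the chromatin assembly gene CHAF1A at 2.21 without erastin. Extracellular matrix genes fell in 18 of 23 cases and rose in 1 without erastin (18 and 1 adjusted over the list alone, median -0.69, adjusted p = 3.44e-07, adjusted p = 0.279 with an estimated correlation), with the fibronectin gene FN1 at -2.54. With no filter on low values that median was -0.42 (adjusted p = 5.82e-06). Cholesterol synthesis genes fell in 17 of 24 cases and rose in 3 (17 and 3 adjusted over the list alone, median -0.57, adjusted p = 0.000215, adjusted p = 0.594 with an estimated correlation). The comparison called 8285 genes without erastin, 4679 higher and 3606 lower (3923 and 4024 after correction for GC content and length), with 1013 past 2-fold. With erastin it called 8576, 5086 higher and 3490 lower, with 1261 past 2-fold, against 3919 higher, 4123 lower and 780 past 2-fold after correction for GC content and length. The median of all genes with erastin was 0.11, and 0.01 with median-ratio scaling, -0.01 with quantile normalization and -0.01 after the correction.

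**Figure D3:**
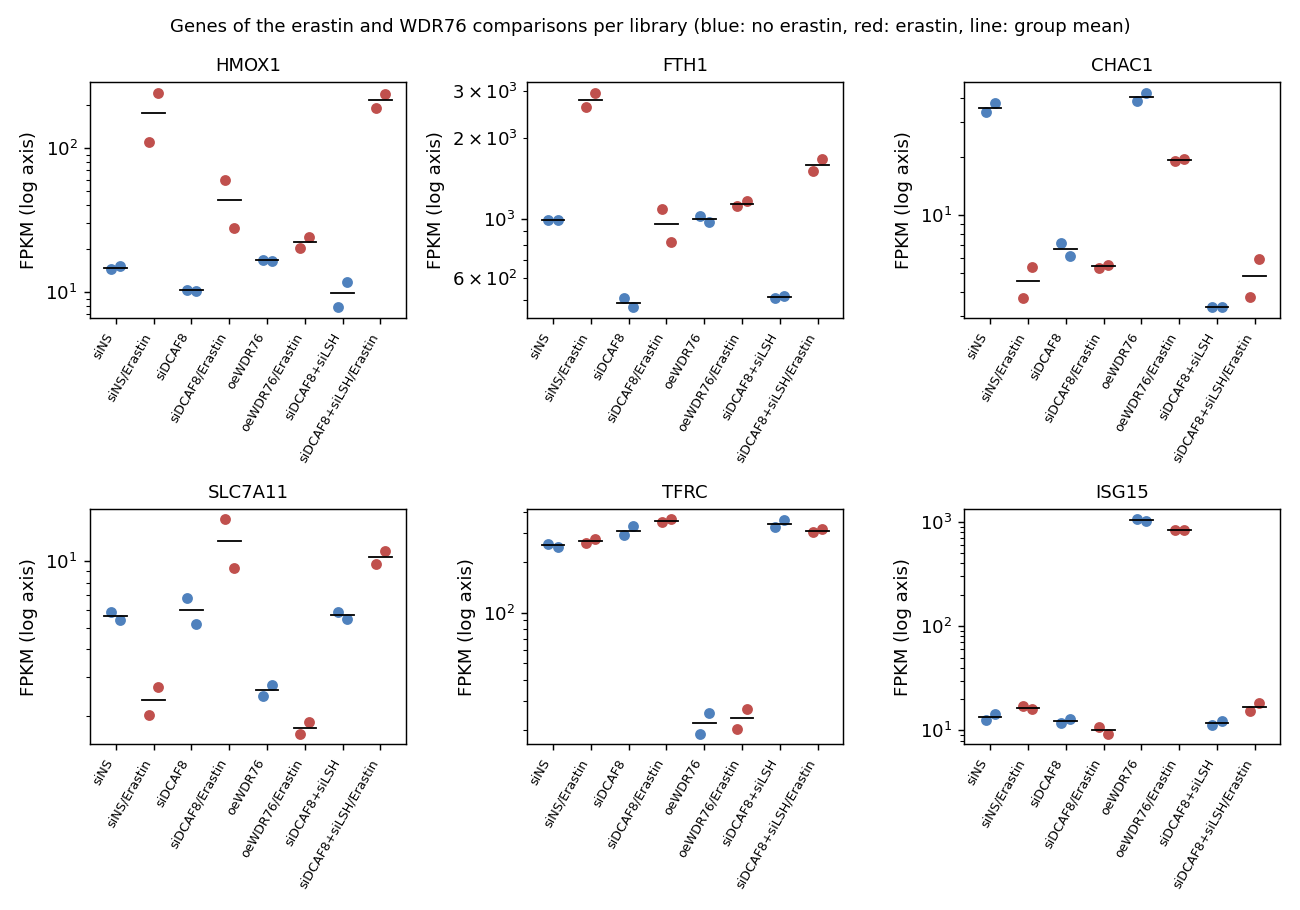
FPKM of HMOX1, FTH1, CHAC1, SLC7A11, TFRC and ISG15 in each library, without erastin in blue and with erastin in red. The line is the mean of n = 2 libraries, and TFRC stands at 22.2 FPKM in oeWDR76 against 252 in siNS.

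The question shared by DCAF8 loss and WDR76 excess is how far their effects on other genes overlap, DCAF8 itself being lower in oeWDR76 as given above. Without erastin 2134 genes rose in both and 1622 fell in both, against 1452 and 1079 under independence, with 1513 moving in opposite directions against 2519. MMP9 and CTGF were among the 10 largest falls of each. The effects correlated at r = 0.358 across genes, with a covariance of 0.0990 against 0.0042 simulated from shared siNS libraries with no effect. With erastin r was 0.284, and the covariance 0.0919 against 0.0042. The simulated r was 0.497 without and 0.501 with erastin, but with no changed genes it is set by the shared libraries alone. It is therefore no baseline for r in these data, and only the covariances can be compared. Pairs that share no library, taken across the erastin states, correlated at 0.291 and 0.203. The siNS or siNS/Erastin libraries, which stood apart on the second principal component, are the reference in all of these pairs. A state common to those libraries would also give such an overlap and cannot be told apart from effects shared by siDCAF8 and oeWDR76. Without erastin, all 30 interferon-stimulated genes rose in oeWDR76 while 21 of them fell in siDCAF8, and G1/S genes rose in 29 and 27 of 29 cases, with the estimated-correlation values given above for each list.

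The comparison of siDCAF8+siLSH with siDCAF8 asks what LSH depletion adds, beside the difference in DCAF8 level given above. FN1 rose 3.26-fold without erastin (SE 0.09, adjusted p = 3.26e-09), from 550 ± 61.9 to 1797 ± 267 FPKM, and 4.24-fold with it (adjusted p = 2.67e-10). HMOX1 was 5.12-fold higher with erastin (SE 0.30, adjusted p = 7.69e-06), at 215 ± 34.2 against 43.9 ± 22.7 FPKM. TXNIP fell 3.86-fold without erastin (SE 0.13, adjusted p = 2.57e-08), from 135 ± 4.38 to 34.3 ± 3.65 FPKM, and DDIT3, the stress factor CHOP, fell 2.68-fold (adjusted p = 1.48e-08) and 2.82-fold with erastin (adjusted p = 4.92e-09). The receptor kinase gene AXL was 2.65-fold lower with erastin (adjusted p = 1.10e-09), at 97.6 ± 9.23 against 260 ± 16.7 FPKM.

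Of 29 G1/S genes, 26 rose without erastin (27 adjusted over the list alone), by a median of 0.53 (adjusted p = 8.71e-11, adjusted p = 0.202 with an estimated correlation), and 27 with it (28 adjusted over the list alone), by 0.59 (adjusted p = 2.76e-10, adjusted p = 0.211 with an estimated correlation). Replication-dependent histones fell in 4 of 7 cases without erastin (4 adjusted over the list alone), by a median of -0.77 (adjusted p = 0.00831, adjusted p = 0.187 with an estimated correlation), or -0.08 with no filter on low values. With erastin their median was -0.64, a call lost with no filter on low values (adjusted p = 0.313). Epithelial markers fell in 3 of 5 cases without erastin (3 adjusted over the list alone), by a median of -0.23 (adjusted p = 0.0314, adjusted p = 0.245 with an estimated correlation, adjusted p = 0.0868 with no filter on low values). Respiratory chain genes rose in 25 of 30 cases without erastin (26 adjusted over the list alone), by a median of 0.33 (adjusted p = 3.70e-10, adjusted p = 0.217 with an estimated correlation), with NDUFA1 at 0.79. Heat shock genes rose in 14 of 17 cases without erastin (14 adjusted over the list alone), by a median of 0.38 (adjusted p = 7.65e-06, adjusted p = 0.183 with an estimated correlation). Targets of p53 fell in 18 of 25 cases and rose in 3 without erastin (18 and 4 adjusted over the list alone), by a median of -0.35 (adjusted p = 1.25e-05, adjusted p = 0.216 with an estimated correlation). With erastin 11 fell and 5 rose (11 and 5 adjusted over the list alone), by a median of -0.03 (adjusted p = 0.0174, adjusted p = 0.538 with an estimated correlation). After correction for GC content and length that median was -0.14 (adjusted p = 0.00907). The calls numbered 5422 without erastin, 2977 higher and 2445 lower, and 5600 with it, 3424 higher and 2176 lower. With erastin the split was 2727 and 2774 with median-ratio scaling and 2868 and 2789 after correction for GC content and length.

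Whether siDCAF8+siLSH returns genes moved in siDCAF8 toward siNS was asked of genes past 2-fold in siDCAF8. DCAF8 depletion in siDCAF8+siLSH was weaker than in siDCAF8, by 0.37 on the log2 scale without erastin and 0.54 with it. A return in any of the pairs below therefore cannot be credited to LSH depletion alone. Since the siDCAF8 libraries enter both contrasts, some return arises from the choice of genes alone. Of 337 such genes without erastin, 126 moved back, 76 moved further and 135 were not called. With erastin, 267 of 490 moved back, 55 moved further and 168 were not called. The median share of the siDCAF8 effect was -7.7% without and -21.1% with erastin. In pairs that share no library, taken across the erastin states, 148 of the 337 moved back and 67 further, and 184 of the 490 moved back and 85 further, with median shares of -12.1% and -8.7%. A state common to the siDCAF8 libraries without and with erastin could still give a return in these pairs. SLC7A11 did not return, and in siDCAF8+siLSH with erastin it stood 1.77 above siNS on the log2 scale (adjusted p = 6.87e-08). Over all genes the 2 effects correlated at r = -0.121 without erastin and -0.336 with it. Shared siDCAF8 libraries with no changed genes gave -0.503 and -0.495 in simulation, which are no baseline for r here either. The covariance was -0.0166 against -0.0043 simulated without erastin, and -0.0523 against -0.0042 with it. Without erastin 2081 genes moved in opposite directions against 1649 under independence, and with it 2783 against 1784.

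The comparison of siDCAF8+siLSH with siNS asks what both siRNAs do together, with HELLS RNA at the siNS level without erastin. CDC6 rose 4.65-fold without erastin (SE 0.08, adjusted p = 4.39e-12), from 6.39 ± 0.184 to 33.4 ± 3.30 FPKM, and NOLC1 rose 5.34-fold. CA9 fell 11.4-fold (SE 0.13, adjusted p = 4.39e-12), MMP9 10.4-fold, and PLAT, the tissue plasminogen activator, 8.54-fold (adjusted p = 5.27e-13), from 172 ± 5.75 to 19.3 ± 1.40 FPKM. CHAC1 fell 8.45-fold without erastin (adjusted p = 3.23e-11). With erastin FN1 was 3.53-fold higher and CCL5 8.84-fold lower. G1/S genes rose in 28 of 29 cases without erastin (28 adjusted over the list alone), by a median of 1.10 (adjusted p = 5.65e-14, adjusted p = 0.183 with an estimated correlation). The ATF4 list fell in 27 of 35 cases and rose in 1 without erastin (27 and 1 adjusted over the list alone), by a median of -0.52 (adjusted p = 2.27e-07, adjusted p = 0.518 with an estimated correlation). Hypoxia genes fell in 14 of 17 cases and rose in 1 (14 and 1 adjusted over the list alone), by a median of -0.49 (adjusted p = 0.000246, adjusted p = 0.233 with an estimated correlation). The calls numbered 7519 without erastin, 4041 higher and 3478 lower, and 7434 with it, 4423 higher and 3011 lower, a split that was 3591 and 3725 with median-ratio scaling.

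**Figure D4:**
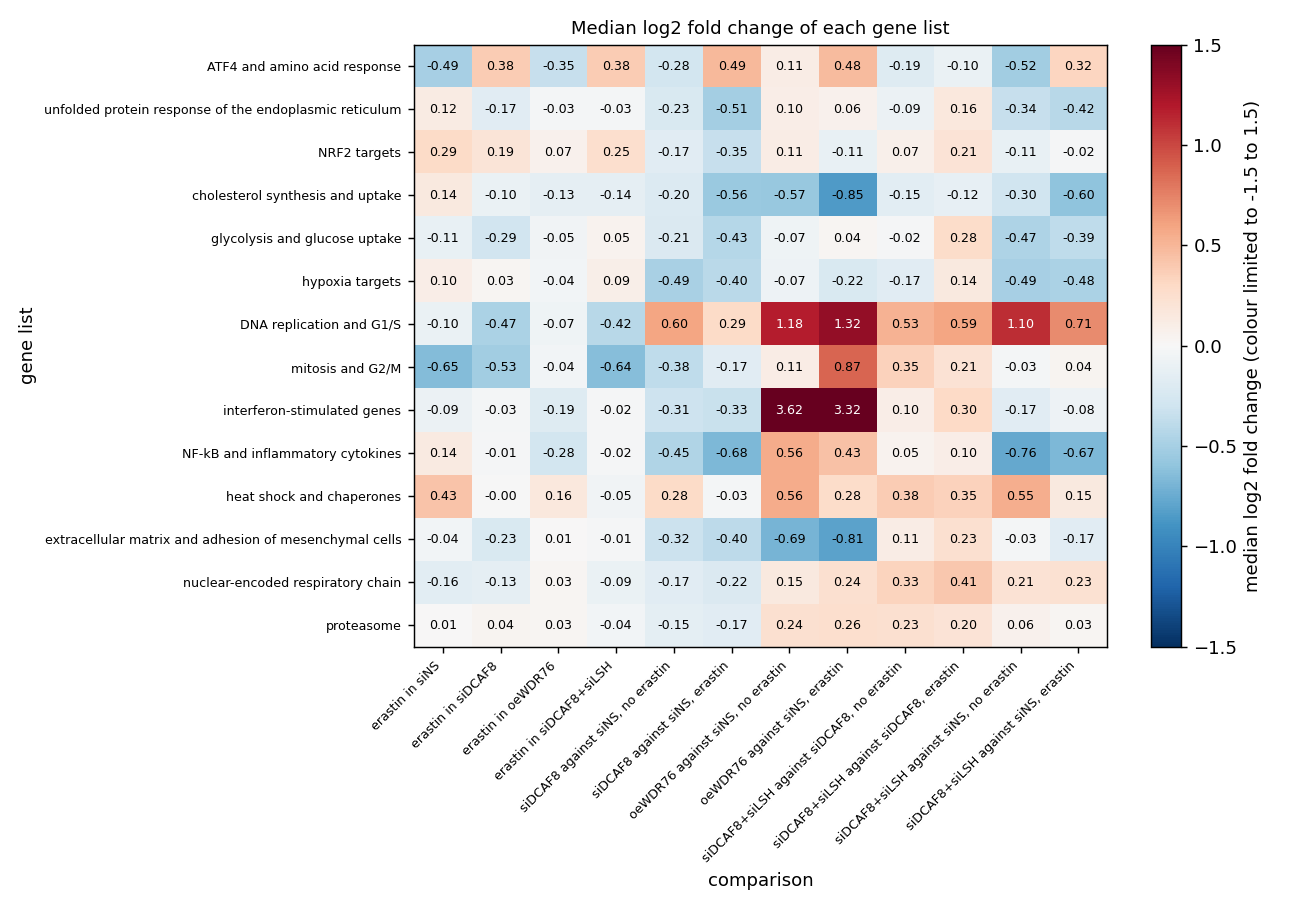
Median log2 fold change of the tested members of 14 gene lists in the 12 comparisons of 2 groups. Colour is limited to the range from -1.5 to 1.5, the value is printed in each cell, and interferon-stimulated genes in oeWDR76 without erastin stand at 3.62 (n = 2 libraries per group). After correction for GC content and length the medians in oeWDR76 without erastin turned for the ATF4 list (-0.14), NRF2 targets (-0.12), the respiratory chain (-0.13) and the proteasome (-0.10), and with erastin for the respiratory chain (-0.02) and the proteasome (-0.03).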

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

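The tests of the ATF4 list in siNS, of myeloid and antigen-presenting markers and of the smaller response in oeWDR76 were chosen only after the results they bear on were seen, as was the correction for GC content and length, while the first immune markers and the vector control were set before. Apart from the interferon-stimulated genes in untreated oeWDR76, weighed for their size, each result in this part stands out because the erastin effect differed between 2 genotypes by a direct test of the difference, which takes in a biological difference of the genotypes that no further experiment here tests.

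ATF4 and amino acid response genes fell after erastin in siNS and oeWDR76 (medians -0.49 and -0.35) and rose in siDCAF8 and siDCAF8+siLSH (each 0.38), calls that are lost at adjusted p = 0.348, 0.183, 0.518 and 0.245 with an estimated correlation. A swap of the siNS and siNS/Erastin labels is argued against by the genes outside the list, whose erastin changes in siNS correlated with the mean of the other 3 genotypes at r = 0.473, where a swap would make this negative. GC content and transcript length as the whole cause are argued against by the list median after correction, -0.43, with quartiles of -0.99 and -0.16. A high list level in untreated siNS cells, such as nutrient shortage in those cultures could give, stays open and cannot be told apart from an erastin effect: untreated oeWDR76 stood 0.11 above siNS (-0.14 after correction for GC content and length), and untreated siDCAF8 and siDCAF8+siLSH stood at -0.28 and -0.52. A genotype-specific response stays open beside it.

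Interferon-stimulated genes were higher in oeWDR76, with a median of 3.62. GC content and length as the whole cause are argued against by the median after correction, 3.52, with quartiles of 1.84 and 4.65. Immune cells in the oeWDR76 cultures stay open by the markers set first, whose highest mean was 4.47 FPKM for LYZ against 3.66 in siNS (adjusted p = 0.0992), and CD3E rose to 1.93 FPKM, so T cells are not excluded. Myeloid or antigen-presenting cells, a set picked because the first left the question open, are argued against by a highest mean of 0.21 FPKM over TYROBP, CD14, CD74 and HLA-DRA, although CD68 rose from 109 to 157 FPKM, beside 13 interferon-stimulated genes of at least 100 FPKM. A response to the vector or its delivery may equally give this pattern and cannot be told apart from an effect of WDR76, since 0 of the 16 libraries carry an empty vector.

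Erastin moved fewer genes in oeWDR76 than in siNS, and HMOX1, FTH1 and the mitosis genes moved less by direct tests. Larger replicate spread in oeWDR76 is argued against by a ratio of median replicate SDs of 0.866 to siNS. The size of the response, taken as the spread of log2 fold changes over genes less the replicate noise, was 0.084 against 0.215 in siNS and 0.144 in siDCAF8+siLSH, a ratio to siNS of 0.39, and of 0.358 after correction for GC content and length (0.337 to 0.392 with any 1 of the 8 libraries left out), which argues against that bias. Untreated levels in oeWDR76 already at the erastin level are argued against by a ratio of 0.399 (0.366 to 0.438) over 4647 genes with like untreated levels. That ratio does not speak for genes whose untreated levels differed. The heat shock list, for example, had a higher median level in untreated oeWDR76 than in siNS/Erastin. A slope on the siNS response, tried first, gave 0.178 in oeWDR76 and was set aside since siDCAF8+siLSH gave 0.184. The measure of size was thus chosen after that slope was seen, and by the slope oeWDR76 did not stand apart from siDCAF8+siLSH. A weaker erastin response of oeWDR76 cells may be a biological difference, as a hypothesis found and tested on the same data, and the missing vector control leaves its link to WDR76 open.

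Between siDCAF8 and siNS the erastin response differed in 2341 genes. List medians of the difference were 1 for ATF4 and amino acid response, -0.37 for the unfolded protein response, -0.18 for NRF2 targets, -0.26 for cholesterol synthesis and uptake, -0.13 for glycolysis, -0.36 for DNA replication and G1/S, 0.11 for mitosis, -0.42 for heat shock, -0.15 for extracellular matrix and -0.56 for replication-dependent histones, and none of these lists passed with an estimated correlation. The largest positive differences on the log2 scale were DRD5 2.84, SSX2 2.72, CHAC1 2.49, INHBE 2.09, CTH 1.94, SLC7A11 1.90, C5AR1 1.81, GPT2 1.76, SLC1A4 1.76 and SCHIP1 1.71. The largest negative ones were NRSN1 -1.74, CCL3 -1.62, SDF2L1 -1.52, HMOX1 -1.49, HSPA1B -1.46, URGCP-MRPS24 -1.41, PLK2 -1.33, PRG2 -1.23, HSPA1A -1.19 and CDC25A -1.11. The mitosis list was no longer called after correction for GC content and length (0.08, adjusted p = 0.18) or in a fit of only the groups compared (0.11, adjusted p = 0.0515). Extracellular matrix was no longer called after that correction (-0.105, adjusted p = 0.203), with quantile normalization (-0.16, adjusted p = 0.0687) or with the stricter filter (-0.15, adjusted p = 0.0539). The glycolysis median was -0.09 after correction for GC content and length and -0.20 with a pseudocount of 0.1, and the histone list was no longer called with no filter on low values (-0.10, adjusted p = 0.054). DRD5, SSX2, HSPA1A, HSPA1B and URGCP-MRPS24 share reads with paralogs or overlapping transcripts and are uncertain.

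Between oeWDR76 and siNS it differed in 1593 genes. List medians of the difference were 0.23 for ATF4 and amino acid response, -0.11 for the unfolded protein response, -0.30 for NRF2 targets, -0.35 for cholesterol synthesis and uptake, -0.10 for hypoxia targets, 0.64 for mitosis, -0.076 for interferon-stimulated genes, -0.32 for NF-kB targets, -0.15 for immediate early genes, -0.29 for heat shock, 0.18 for the respiratory chain and -0.40 for replication-dependent histones, and none of these lists passed with an estimated correlation. After correction for GC content and length the medians were -0.15 for hypoxia targets, -0.23 for immediate early genes, -0.12 for interferon-stimulated genes and 0.11 for the respiratory chain. The hypoxia list was no longer called with that correction (adjusted p = 0.0508), quantile normalization (adjusted p = 0.0562), the stricter filter (adjusted p = 0.084) or only the groups compared (adjusted p = 0.0729). The interferon-stimulated list was -0.16 with quantile normalization and -0.15 with the stricter filter, and was no longer called with a pseudocount of 0.1 (-0.02, adjusted p = 0.0508), while the histones were at -0.68 with that pseudocount and no longer called with no filter on low values (adjusted p = 0.724). Positive differences were largest for SSX2 3.77, CHAC1 1.70, FAM25A 1.53, DDIT4 1.44, RANBP3L 1.25, INHBE 1.22, FRG2 1.199, ALG1L2 1.18, GMFG 1.15 and JDP2 1.13. Negative ones were largest for SSX2B -3.39, HMOX1 -2.99, URGCP-MRPS24 -2.26, CCL3 -1.87, S100P -1.67, PRG2 -1.34, FTH1 -1.30, NRSN1 -1.28, C10orf10 -1.25 and ALOX5AP -1.18. SSX2, SSX2B, FRG2, FAM25A, ALG1L2 and URGCP-MRPS24 are uncertain for shared reads.

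Between siDCAF8+siLSH and siDCAF8 it differed in 2642 genes, and in 265 after correction for GC content and length. The median difference was 0.17 for NRF2 targets and 0.23 for glycolysis, or 0.09 and 0.13 after the correction, the NRF2 list was no longer called with the stricter filter (0.13, adjusted p = 0.0938), and neither list passed with an estimated correlation. Positive differences were GAGE12I 3.46, HMOX1 2.45, NRSN1 2.04, ZNF485 1.66, FPR1 1.5, GAGE12F 1.42, CA9 1.33, CBSL 1.14, PAEP 0.99 and MAGEA2 0.96. Negative ones were SCHIP1 -2.29, LOC101060389 -1.70, SGK3 -1.10, EIF4EBP3 -0.999, LOC389831 -0.93, RPL17-C18orf32 -0.91, MYBL1 -0.85, UAP1 -0.84, RPL22L1 -0.83 and RND3 -0.81. After correction for GC content and length GAGE12F, CBSL, PAEP, MAGEA2, LOC101060389, SGK3, EIF4EBP3 and RPL17-C18orf32 were no longer called, and GAGE12I, GAGE12F, CBSL, MAGEA2, RPL17-C18orf32 and the LOC genes are uncertain for shared reads.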

How the results depend on the processing

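The correction for GC content and transcript length and all counts of genes past 2-fold were chosen after the results were seen, and the other alternatives were planned. In the order of erastin in siNS, siDCAF8, oeWDR76 and siDCAF8+siLSH, then siDCAF8 against siNS without and with erastin, siDCAF8+siLSH against siDCAF8 without and with erastin, siDCAF8+siLSH against siNS without and with erastin, and the differences of erastin response of siDCAF8 and oeWDR76 from siNS and of siDCAF8+siLSH from siDCAF8, a pseudocount of 0.1 gave 127, 85, 10, 55, 569, 827, 186, 221, 894, 832, 121, 73 and 44 genes past 2-fold, as low values are shrunk less. No filter on low values, which tests more genes, called 84 genes with erastin in oeWDR76 and 1755 in the difference between siDCAF8+siLSH and siDCAF8. A fit of only the groups compared gave 270 and 1696 for the same results. The stricter filter of mean FPKM at least 5 left 1, 21 and 4 genes past 2-fold for erastin in oeWDR76 and the differences of oeWDR76 from siNS and of siDCAF8+siLSH from siDCAF8. With the correction for GC content and length, 780 genes passed 2-fold in oeWDR76 against siNS with erastin, and 265 genes were called and 6 passed 2-fold in the difference between siDCAF8+siLSH and siDCAF8. The cause of the other shifts was not tested.

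Only the correction for GC content and length, which removes that trend by construction, turned the direction of called named genes. These were RPLP2 (0.08) in siDCAF8 against siNS with erastin, RPS2 (-0.18) and HIST1H1C (-0.023) in oeWDR76 without erastin, CTAG2 (-0.32), RPS2 (-0.28), RPLP2 (-0.11), KRT18 (-0.14), PECAM1 (0.025), PSMB3 (-0.022) and PSMA7 (-0.071) in oeWDR76 with erastin, RPL35 (-0.087) in siDCAF8+siLSH against siDCAF8 with erastin, and GPX4 (-0.001), DCAF15 (-0.013), TRIM28 (-0.005) and RPL8 (-0.046) in the difference between siDCAF8+siLSH and siDCAF8. The correlation of erastin effects between siDCAF8 and siDCAF8+siLSH became 0.651 with it, and that of siDCAF8 and oeWDR76 effects 0.420 without erastin, 0.386 with it, and 0.357 and 0.286 across the erastin states. The correlation between erastin effects in siNS and oeWDR76 was 0.265 with a pseudocount of 0.1 and 0.438 with the stricter filter, which gave 0.259 for siDCAF8 and oeWDR76 effects with erastin. With the estimated correlation between genes 3 of the list tests passed.

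Leaving out each library in turn, where the lone library of a group is assumed to vary like the others, gave 2796 to 3277 genes for erastin in siNS, 3021 to 3978 in siDCAF8, 27 to 39 in oeWDR76 and 1247 to 2098 in siDCAF8+siLSH. The differences of response gave 1315 to 2330 for siDCAF8 and 906 to 1313 for oeWDR76 from siNS, and 1008 to 3003 for siDCAF8+siLSH from siDCAF8. Past 2-fold were 33 to 45 genes for erastin in siDCAF8, 3 to 6 in oeWDR76 and 9 to 26 in the last difference. Of the named genes, 332 results under other settings and 720 with a library left out were no longer called, against 12431 and 6956 that kept their direction and their side of the threshold. The counts in the 8 comparisons between genotypes stayed within 1.5 times under all alternatives but for genes past 2-fold as given. Which genes were called changed more. With the GC and length correction, 6181 of 8285 calls in oeWDR76 against siNS without erastin kept their direction, and 6118 of 8576 with it. Past 2-fold in both fits were 535 and 593 genes. In siDCAF8+siLSH against siDCAF8 without erastin 3931 of 5422 calls were kept, and in siDCAF8 against siNS without erastin 6541 of 6863. GC content and length held 19.1%, 22.3%, 17.3% and 1.5% of the variance across genes, in that order. For erastin in siDCAF8, where they held 21.7%, 2896 of 4600 calls were kept. Replicate numbers are not shown to pair the libraries, and as a block they gave 4286 genes for erastin in siNS and 156 in oeWDR76. The deposited table gives no depth, so no limit from counting is given.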
